A study of Mus musculus with 4 samples.

How the data were processed

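Gene expression was measured in 4 samples of HL-1 cells, 2 transfected with CD56-140kD and 2 mock-transfected, each on 1 array. Per the labels' protocols, adherent cells were transfected with FuGENE and plasmids carrying CD56 isoform cDNA and incubated for 18 h, total RNA was isolated with TriPure, and biotin-labelled cRNA was prepared by the Affymetrix protocol. What the mock cultures received, the species of the cDNA and the MAS5 version are not given in the sources used here. Per the submitters' processing notes the signals were computed with MAS5. The deposited values are on a log2 scale: 2 raised to the value had a 2% trimmed mean of 500 on every array, so each array had been scaled to a common level before deposit. The scale and its base were read from the values. The lowest value was 0, at 301 to 508 probe sets per array. The number of arrays limits the precision.

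Samples were grouped by the labels. The series text says that each of the 2 replicate experiments held 1 sample of each group, so samples of the same replicate number were taken as 1 experiment. This pairing comes from the labels, and it was checked once: the deviations of same-numbered arrays from their group means correlated with r = -0.034 across probe sets. A fit with the replicate block called 0 probe sets too, with 327 at an unadjusted p under 0.05. Nothing beyond the word experiment says how separate the cultures were, so the spread may be partly technical.

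The values were used as deposited, with no pseudocount because they already were logarithms. Of 45101 rows, 64 control probe sets were left out, and of the 45037 others the upper 50% by mean over all arrays were kept, 22518 probe sets with a mean of at least 5.81. Gene names came from the platform annotation, in which 34945 probe sets had 1 symbol, 932 had several and 9160 had none. Through gene identifiers 34754 symbols matched the reference gene table of assembly GRCm38.p6, and 0 needed updating. Probe sets with several symbols named no gene. A gene was represented by its brightest kept probe set, which gave 11103 genes, and other kept probe sets are given for Ncam1 and the 17 genes that the rule named by size of difference. No genomic coordinates are printed because the array values name no genome build. For the same reason the values of a comparison of gene lengths, as genomic spans, run on the genes low in mock replicate 1 are left out, since the table served for names only.

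Differences were fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), all 4 arrays and no block, two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. A fold is 2 raised to the log2 difference. Probe sets at least 2-fold different in the same and in opposite directions in the 2 experiments were counted without a test. The 26 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists with at least 5 genes measured, and beside it with an estimated correlation and with fry. With an estimated correlation camera judges a list on the residual degrees of freedom, of which 4 arrays in 2 groups leave very few. That version could hardly keep any call here, so a call lost with it decides little. Camera compares a list with all other genes, so a list called lower lay below the others and not always below mock. Fry instead tests a list by itself, which is another question. Plots were drawn with matplotlib 3.10.9.

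The groups, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where stated. The rule named Ncam1, then per direction up to 12 genes past the threshold, filled up with genes at an unadjusted p under 0.01 whose groups did not overlap and whose experiments had the same direction, by size of difference. As 0 genes passed, all 12 higher and 5 lower genes come from the second part and did not pass. From each list described, the 2 members with the smallest p were named. For ribosomal proteins this departs from the plan, which had kept them to a list summary. The limma fit was tested on simulated data in 20 runs of 22518 probe sets with 200 changed each. It recovered 0.1% of 2-fold, 6.6% of 4-fold, 39.1% of 8-fold and 68% of 16-fold changes, with 6% of calls false. Camera found 20 of 20 simulated lists of 30 genes raised by 1 log2 unit and 0 of 20 unchanged lists. The simulated noise was independent between probe sets, so these lists had no correlation between genes. They do not show how often camera falsely calls lists of correlated genes, and the estimated correlation of the real lists reached 0.53.

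The alternatives were the replicate block, quantile normalization, centring on the median, added constants of 16 and 64 on the linear scale, no filter, the upper 30% of probe sets, no variance trend, leaving out each array, folds of 1.5 and 3, and, for lists, the mean of all kept probe sets of a gene. A count over the upper 10% of probe sets was added after seeing the data. For a fit without 1 array the group left with a single array was assumed to vary like the other.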

Results

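The arrays measured transcript levels in HL-1 cells, a mouse cardiomyocyte line of atrial origin. CD56 is another name for NCAM1, the neural cell adhesion molecule, a cell-surface glycoprotein made in several isoforms by alternative splicing. Cells transfected with a plasmid for the isoform named CD56-140kD were compared with mock-transfected cells after 18 h. There were 2 replicate experiments, each with 1 array of each group, so n = 2 per group. The comparison asks which transcripts differ when cardiomyocytes receive this isoform. The deposited values were log2 MAS5 signals, and all differences below are CD56-140kD minus mock on that scale. Over the 22518 probe sets kept, the median log2 signal was 8.74 and 8.67 in CD56-140kD replicates 1 and 2 and 8.43 and 8.69 in mock replicates 1 and 2. Pairs of arrays correlated across probe sets with r from 0.903, between the 2 mock arrays, to 0.958, between CD56-140kD replicate 1 and mock replicate 2.

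Ncam1, the gene of the transfected protein, was read by 4 kept probe sets, and none passed the test. The brightest had a log2 signal of 10.07 ± 0.10 (SD, n = 2) with CD56-140kD and 9.78 ± 1.01 (SD, n = 2) in mock, a difference of 0.28 (SE 0.52), or 0.13 after median centring and 0.18 after quantile normalization. Another showed the widest gap, 1.27 (SE 0.57, 2.42-fold), with 9.14 and 8.21 against 6.81 and 7.99. The other 2 kept probe sets differed by 0.64 (SE 0.56) and 0.47 (SE 0.45). The groups did not overlap for 2 of the 4 probe sets. The labels do not give the species of the transfected cDNA, so these mouse probes may not read it. Without mock replicate 1 the difference of the brightest probe set was -0.43, the opposite direction.

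Emp2, a tetraspan membrane protein, and Reck, a membrane-anchored inhibitor of matrix metalloproteinases, were among the 12 genes higher with CD56-140kD that the naming rule took. The rule's limit, an unadjusted p under 0.01 in limma, was met by 35 probe sets in both directions together, where chance alone gives 225. The Emp2 log2 signal was 10.26 ± 1.32 with CD56-140kD and 6.41 ± 0.37 in mock (SD, n = 2 each), a 14.4-fold difference (log2 3.85, SE 0.64). All 3 Emp2 probe sets kept lay higher, by 3.85 to 4.47. The dimmer ones read 3.67 and 2.1 in mock replicate 2, within the range of control probe sets with no mouse target, so their folds are uncertain. For Reck the levels were 8.25 ± 0.99 and 4.66 ± 0.53 (SD, n = 2 each), a log2 difference of 3.59 (SE 0.65). The mean Reck signal in mock lay within the range of control probe sets with no mouse target, which read up to 4.74, so its fold is uncertain, and added constants of 16 and 64 gave 2.96 and 2.06. Synpo2l, a Z-disc protein of striated muscle, was 5.14-fold higher (log2 2.36, SE 0.57), and so was its other probe set, by log2 2.16. Mybpc3, the cardiac myosin-binding protein C of the thick filament, stood at 12.53 ± 0.38 against 11.14 ± 0.57 (SD, n = 2 each), 2.63-fold higher with an SE of 0.40. None of these genes passed the test, and limma's adjusted p was 1 for each.

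Dusp3, a dual-specificity phosphatase that acts on MAP kinases, was 3.94-fold higher (log2 1.98, SE 0.50), and its 3 probe sets lay higher by 0.73 to 3.12. The probe set with 3.12 read 3.71 and 4.81 in mock, within or near the range of controls with no target, so that value is uncertain. Dnm1, the GTPase dynamin 1 of endocytosis, was 3.66-fold higher, with 7.30 ± 0.14 against 5.43 ± 0.04 (SD, n = 2 each). Ntn1, the guidance cue netrin 1, was 2.22-fold higher (log2 1.15, SE 0.32), with 12.92 ± 0.36 against 11.77 ± 0.09 (SD, n = 2 each), and its other probe set differed by 0.55 (SE 0.42). The same rule took the carbonyl reductase Cbr3 at log2 2.03, the POU-domain transcription factor Pou6f1 at 1.77, the ubiquitin ligase Rnf125 at 1.74 and the protocadherin Pcdhb21 at 1.59. Pcdhb21 belongs to a family of similar genes, so its signal may include relatives. The rule also took Samd5, at 7.03 ± 0.94 against 4.63 ± 0.35 (SD, n = 2 each), where the mock mean again lay within the range of controls with no target, and the difference of 2.40 became 1.16 with an added constant of 64. The same constant lowered the log2 difference of Dnm1 to 1.05, of Cbr3 to 1.26 and of Pou6f1 to 1.06. The 12 genes lay higher in both experiments because the rule required it, and each had an adjusted p of 1 in limma.

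Only 5 genes met the same rule in the lower direction. Pf4, a chemokine of platelets and macrophages, had log2 signals of 5.44 and 5.42 with CD56-140kD against 10.04 and 7.27 in mock, a 9.36-fold difference (log2 -3.23, SE 0.85). Lgals2, a galactose-binding lectin, was lower by 4.6-fold (log2 -2.20, SE 0.47), and its other probe set differed by -0.86. Parm1, a mucin-like membrane protein, stood at 6.08 ± 0.48 against 8.15 ± 0.01 (SD, n = 2 each), a log2 difference of -2.07. The microsomal glutathione transferase Mgst2 differed by -1.36 (SE 0.39). The Wnt receptor Fzd6 differed by -1.29 (SE 0.37), with -1.08 at its other probe set. With an added constant of 64 the log2 differences were -2.21 for Pf4, -1.69 for Lgals2 and -1.39 for Parm1, so their folds are uncertain. Mgst2 and Fzd6 changed less with that constant, to -1.24 and -1.27. None passed, each with an adjusted p of 1 in limma. The Pf4 difference depended on the mock arrays: it was -1.84 without mock replicate 1, and -4.61 without mock replicate 2, where limma called it (adjusted p = 0.046).

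**Figure D1:**
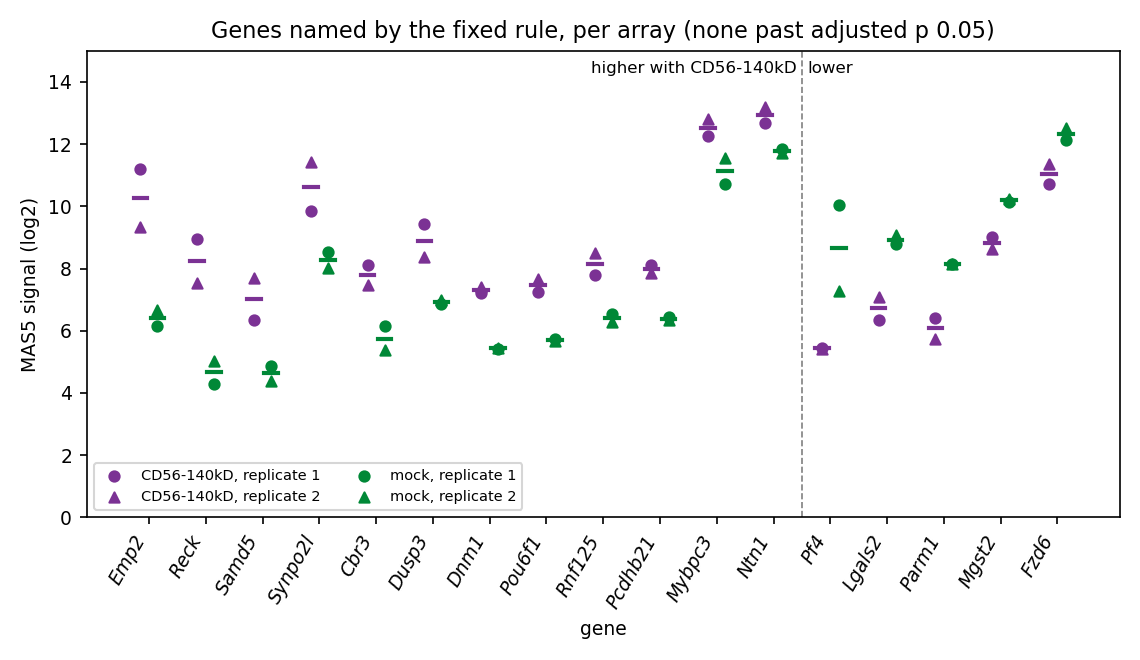
Log2 MAS5 signal (y axis) of the 17 genes named by the fixed rule (x axis), with 1 point per array, circles for replicate 1, triangles for replicate 2, and a line at each group's mean of 2 arrays. CD56-140kD and mock arrays do not overlap for any of these genes because the rule required it, and the 2 mock arrays of Pf4 lie apart, at 10.04 and 7.27.

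Over all probe sets, limma called 0 of 22518 at an adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 263 probe sets, 214 higher and 49 lower, where chance alone gives 1126. Under 0.01, the limit of the naming rule, there were 35, where chance alone gives 225. The groups did not overlap at 24.4% of probe sets, where chance gives 33.3%. The median difference of all kept probe sets was 0.093, and centring each array on its median moved it to -0.056. Among the alternatives run, calls appeared only when an array was left out: 19 probe sets without mock replicate 2, among them Cav3, Gata5 and Pf4, and 1, for Cd9, without CD56-140kD replicate 2. In these fits 1 group is a single array, taken to vary like the other group, and without mock replicate 2 it is mock replicate 1, which lay at least 2-fold below all other arrays at 1622 probe sets. With 2 arrays per group the test had little power for small changes in simulated data, recovering 0.1% of 2-fold changes and 39.1% of 8-fold ones. The simulated noise was independent and held no differences between experiments or single arrays, so the power in the real arrays may differ.

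Within the experiments, Emp2 differed by 5.04 in experiment 1 and 2.65 in experiment 2, Reck by 4.66 and 2.52, and Pf4 by -4.60 and -1.85. The naming rule had required the same direction in both experiments for these genes. At least 2-fold in the same direction in both experiments were 219 probe sets, 180 higher and 39 lower with CD56-140kD. At least 2-fold in opposite directions were 696, of which 548 were higher in experiment 1 and lower in experiment 2. The differences of the 2 experiments correlated across probe sets with r = -0.25, and probe sets are not independent replicates. The lean towards higher depended on scaling: after quantile normalization 92 probe sets were higher and 85 lower in both experiments, and after median centring 113 and 68.

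**Figure D2:**
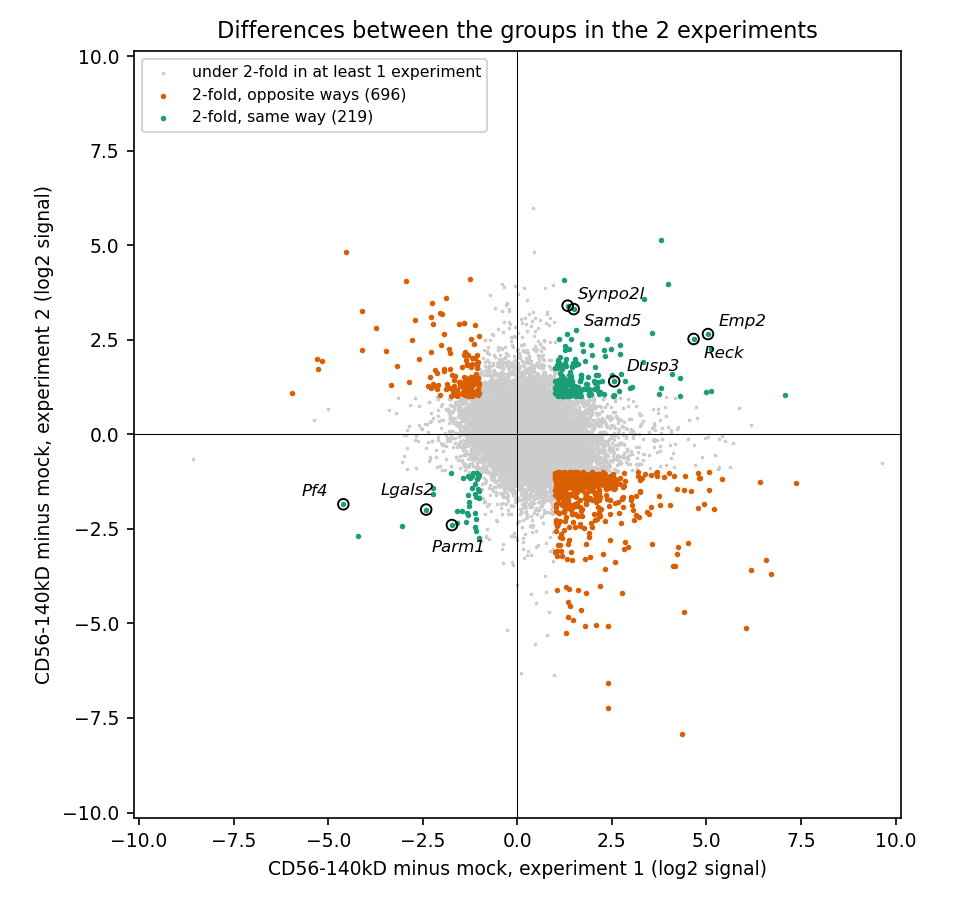
Difference CD56-140kD minus mock in log2 signal in experiment 1 (x axis) and in experiment 2 (y axis), with 1 point per kept probe set. Green points are the 219 probe sets at least 2-fold different in the same direction, orange points the 696 in opposite directions, and circles mark 8 of the named genes.

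Sarcomere genes had a higher median with CD56-140kD and were called by camera, though not with an estimated correlation. Of 27 measured members, 16 were higher in both experiments, 1 was lower in both and 10 went opposite ways, with a median difference of 0.43 (0.28 after centring), or 0.34 in experiment 1 and 0.31 in experiment 2. The members with the smallest p were Mybpc3, 2.63-fold higher (SE of log2 0.40), and Xirp1, an actin-binding protein of striated muscle, 2.06-fold higher (SE of log2 0.46). Larger log2 differences, picked afterwards, rested on single arrays. Myh6, at 4.05 (SE 2.88), read 2.7 in mock replicate 1 and 9.77 to 14.05 elsewhere. Actn2, at 2.63 (SE 1.34), read 14.25 in CD56-140kD replicate 2 and 8.78 to 9.42 elsewhere. No member passed alone, over all genes or adjusted over the list alone. The list was called by limma's camera test (adjusted p = 0.019), and the call was lost with an estimated correlation (adjusted p = 0.98). With 4 arrays the latter version could hardly keep any call, so that loss decides little. It was also lost without CD56-140kD replicate 2 (adjusted p = 0.35) and without mock replicate 1 (adjusted p = 0.82), where the median was 0.11 and -0.04. All 6 list calls made with camera, here and below, were also lost with fry, without the filter on dim probe sets and without the variance trend. The list's median per array was 9.77 and 11.14 with CD56-140kD and 9.58 and 10.79 in mock, so replicate 2 was the higher array in both groups.

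The calcium and ion-channel list and the natriuretic and hypertrophy list had medians above 0, at 0.15 and 0.21 after centring. Neither passed in the camera test as fixed in advance. Among 26 calcium-handling and ion-channel genes the median was 0.30 (camera adjusted p = 0.23), led by Pln, the SERCA inhibitor phospholamban, at 1.12 (SE 0.58) and the sodium-calcium exchanger Slc8a1, 2.83-fold higher (SE of log2 0.83). Slc8a1 read 5.38 in mock replicate 1 and between 8.15 and 8.34 elsewhere, and an added constant of 64 gave a log2 difference of 0.95. Among 12 genes of the natriuretic and hypertrophy list the median was 0.36 (camera adjusted p = 0.31), with 0.61 in experiment 1 and -0.09 in experiment 2. The growth factor Tgfb2 stood at 1.37 (SE 0.45) and the matricellular gene Ccn2 at 0.99 (SE 0.41). Both medians turned without mock replicate 1, to -0.13 and -0.29. Both lists were called without mock replicate 2 (adjusted p = 0.0078 and 0.0073), and the calcium list also without CD56-140kD replicate 1 (0.0037) and among the upper 30% of probe sets (0.025). Neither list had a member past the test, over all genes or adjusted over the list alone.

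Apoptosis genes and genes of hypoxia and glycolysis were called lower by camera, relative to all other genes. Both calls were lost with an estimated correlation, a version that could hardly keep any call with 4 arrays. The median difference over all kept probe sets was 0.093. Of 23 apoptosis genes 8 were lower in both experiments, 2 were higher in both and 13 went opposite ways, with a median of -0.16. Bid, a pro-apoptotic BCL2 family member, stood at -1.13 (SE 0.48) and the initiator caspase Casp9 at -0.67 (SE 0.42). Of 27 hypoxia and glycolysis genes 7 were lower in both experiments, 3 were higher in both and 17 went opposite ways, with a median of -0.02. After centring the medians were -0.30 and -0.17. Egln3, a prolyl hydroxylase that acts on HIF, stood at -1.31 (SE 0.43) and the glucose transporter Slc2a1 at -0.70 (SE 0.28). Limma's camera gave adjusted p = 0.027 for apoptosis and 0.019 for hypoxia and glycolysis, and adjusted p = 0.98 for both with an estimated correlation. No member of either passed, over all genes or adjusted over the list alone. The apoptosis call was lost without any 1 of the 4 arrays (adjusted p from 0.081 to 0.26), and the other without CD56-140kD replicate 1 (0.62) or mock replicate 2 (0.32). The hypoxia and glycolysis median was 0.03 and 0 without these arrays, -0.17 without CD56-140kD replicate 2 and -0.14 without mock replicate 1, and the apoptosis median was -0.29 to -0.05 without 1 array. Quantile normalization also ended both calls (adjusted p = 0.11 and 0.14).

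Oxidative phosphorylation, ribosomal protein and sterol synthesis genes were called lower by camera, relative to all other genes, though not with an estimated correlation. Their members mostly ran opposite ways in the 2 experiments. For oxidative phosphorylation 40 of 48 genes did so, with medians of -0.36 and 0.21, and 8 were lower in both. The complex I subunits Ndufa1 and Ndufb3 stood at -0.47 (SE 0.28) and -0.48 (SE 0.34), and the list's median was -0.07, -0.22 after centring and 0.01 after quantile normalization. For ribosomal proteins 22 of 27 went opposite ways, with medians of -0.30 and 0.07, or -0.09 over all arrays and -0.24 after centring, and Rpl37 and Rpl14 stood at -0.67 (SE 0.36) and -0.52 (SE 0.45). For sterol synthesis 19 of 21 did so, with medians of 0.19 and -0.70, or -0.11 over all arrays and -0.26 after centring, and the cholesterol synthesis enzymes Ebp and Nsdhl stood at -0.78 (SE 0.42) and -0.84 (SE 0.46). Limma's camera gave adjusted p = 0.019, 0.019 and 0.027 in that order, and adjusted p = 0.98 for each with an estimated correlation. No member passed, over all genes or adjusted over the list alone. Without mock replicate 1 the oxidative phosphorylation and ribosomal calls were lost (adjusted p = 0.98 and 1), as they were without CD56-140kD replicate 1 (0.24 and 0.15). Their medians were 0 and 0.03 without the former array and 0.11 and -0.06 without the latter. The ribosomal call was also lost without CD56-140kD replicate 2 (0.052), and the sterol call without CD56-140kD replicate 2 (0.80) or mock replicate 2 (0.55), and quantile normalization ended all 3 calls (0.97, 0.60 and 0.14).

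Lists tied to NCAM and to cell contacts were not called in the camera test as fixed in advance. The 15 genes of NCAM partners and RUNX factors had a median of 0.23 (camera adjusted p = 0.31), with 0.80 in experiment 1 and -0.14 in experiment 2. Sptan1, the alpha-spectrin of the membrane skeleton, stood at 0.55 (SE 0.38) and protein kinase C alpha, Prkca, at 0.68 (SE 0.49). The 24 cell-junction genes had a median of 0.16 (camera adjusted p = 0.49), with the integrin Itga5 at 0.65 (SE 0.43) and the junctional receptor Cxadr at 0.82 (SE 0.54). The median of the NCAM list in mock replicate 1 was 7.84, and in the other 3 arrays it was 9.01 to 9.14. Without that array the medians of the NCAM and junction lists turned to -0.12 and -0.16. Sptan1, Prkca and Cxadr then stood at 0.13, 0.12 and 0.10, while Itga5 rose to 1.02. Without mock replicate 2 both lists were called (adjusted p = 0.0094 and 0.014), as was the NCAM list among the upper 30% of probe sets (0.039). In the 29 interferon-response genes the median was 0.20 (camera adjusted p = 0.51), with Irf9 at 0.74 (SE 0.58) and Psmb9 at 0.63 (SE 0.52). Without CD56-140kD replicate 2 the interferon list was called (adjusted p = 0.014), and without CD56-140kD replicate 1 or mock replicate 1 its median turned to -0.09 or -0.02. In the 18 heat-shock genes it was 0.20 (camera adjusted p = 0.10), with the chaperones Hsp90aa1 at 1.07 (SE 0.47) and Hspa1b at 0.71 (SE 0.51), and it was called with quantile normalization (adjusted p = 0.0014), among the upper 30% of probe sets (0.034) and without CD56-140kD replicate 1 (0.043). After centring the 4 medians were 0.08, 0.01, 0.05 and 0.05, in the order given. No member of the 4 lists passed, over all genes or adjusted over the list alone.

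Leukocyte genes, fixed as markers of another cell type, were mostly dim: 6 of 20 were measured, with a median of -0.11 (-0.26 after centring, -0.31 after quantile normalization) and a mean of -0.34 (camera adjusted p = 0.23 over 6 genes in limma). Itgb2, the beta chain of leukocyte integrins, read 10.72 in mock replicate 1 and 6.77 to 8.47 in the other arrays, and the macrophage gene Cd68 stood at -0.83 (SE 0.57), or -0.51 with an added constant of 64. The leukocyte list was called lower without CD56-140kD replicate 1 (limma camera adjusted p = 0.034), and its median was 0.40 without mock replicate 1 and 0.11 without CD56-140kD replicate 2. The 12 remaining lists tested had medians from -0.07 to 0.21, or -0.22 to 0.06 after centring, and the smallest camera adjusted p among them was 0.31. Of these lists mitosis alone was called in any alternative, lower without mock replicate 1 (6e-04) and higher without mock replicate 2 (0.0094). They covered cardiac transcription factors, immediate early and ERK targets, NF-kB targets and cytokines, the unfolded protein response, p53 targets, mitosis, DNA replication, fatty acid oxidation, Wnt, Notch and TGF-beta targets, and fibroblast, endothelial and smooth-muscle markers. For p53 targets, mitosis, DNA replication and smooth muscle the signs of median, mean and test differed. The neural list had 3 measured genes and was not tested.

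**Figure D3:**
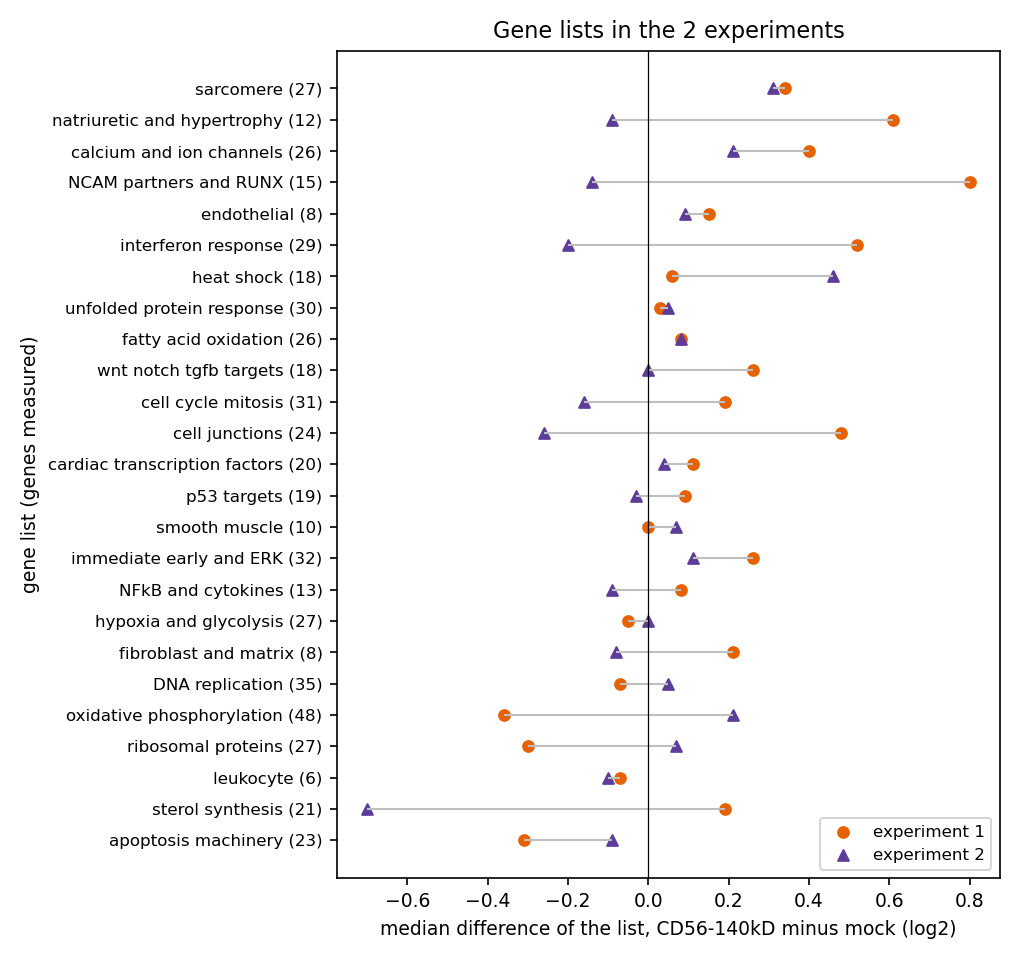
Median difference CD56-140kD minus mock in log2 signal (x axis) for each of the 25 tested gene lists (y axis, number of genes measured in brackets), with circles for experiment 1 and triangles for experiment 2, joined by a line. Sarcomere genes stood at 0.34 and 0.31, and sterol synthesis genes at 0.19 and -0.70.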

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

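The count of the upper 10% was chosen after seeing the data, and the other alternatives were planned. No probe set was called by limma with quantile normalization, median centring, either added constant, no filter, the upper 30%, no variance trend or the replicate block (0 calls; the paired fit changed no call of a probe set or list). Raw log2 signals with values under 1 set to 1 were planned but not run, because they equal the deposited values. Leaving out 1 array gave 0 to 19 probe sets called, and 3 to 8 gene lists, of which 2 or 3 were among the 6. Against 6 lists called with camera there were 2 with quantile normalization (1 of the 6, with heat shock new), 4 with the mean of all kept probe sets of a gene (3 of the 6, with heat shock new), 9 among the upper 30% (the 6 and calcium, NCAM and heat shock), 0 with no filter, 0 with no variance trend (adjusted p = 0.052 for each of the 6), 0 with an estimated correlation and 0 with fry. Without 1 array in turn, the Ncam1 difference ranged from -0.43 to 1.00, the list medians from -0.04 to 0.91 for sarcomere, -0.27 to 0.11 for oxidative phosphorylation, -0.60 to 0.09 for sterol synthesis and -0.24 to 0.47 for mitosis, and the differences from -0.03 to 1.29 for Psmb9, -0.12 to 1.53 for Hspa1b and -3.10 to 0.67 for Itgb2. Ncam1 and Itgb2 turned direction without mock replicate 1, Psmb9 and Hspa1b without CD56-140kD replicate 2. Quantile normalization put the oxidative phosphorylation median at 0.01. Of 502 combinations of a gene named by the fixed rule and a setting, 498 kept the direction and 4 did not. Many could not turn, so the count is no measure of robustness. The replicate block, no filter, the upper 30% and no variance trend leave each log2 difference as it was. Genes taken because their groups did not overlap cannot turn when 1 array is left out. Of 297 combinations of a list and a setting, the camera direction turned in 40. Without 1 array in turn, the log2 difference of Pf4 moved by over 1.5 times. So did those of 23 of the 25 list members that the rule named for their lists alone, Tgfb2 and Slc2a1 being the exceptions. Those of the other 16 genes of the naming rule moved by less, though as folds some moved by more, with log2 2.91 to 4.78 for Emp2 and 2.89 to 4.29 for Reck. The 219 probe sets that differed 2-fold the same way in both experiments became 1043 at 1.5-fold and 28 at 3-fold, 138 and 46 with added constants of 16 and 64, 3542 with no filter, 38 in the upper 30% and 4 in the upper 10%. Each of those settings changes which or how many probe sets can pass; for the list calls and directions the cause was not tested. MAS5 signals of dim probe sets scatter widely, and the TrpnX control probe sets, which have no mouse target, read 0.14 to 4.74.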

Other observations

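The genes that differed between the experiments, and those of the next split, were picked from those with the smallest p after the values were seen. The tests of 5' degradation, of opposite directions and of the splits were chosen after their results were seen. Between the experiments, with both groups pooled, the brown-fat and lipid-droplet gene Cidea was 15.3-fold higher in experiment 2 (6.75 and 6.97 against 10.46 and 11.12), the transcription regulator Id3 12.4-fold, Igfbp5 16.4-fold and the lipoprotein lipase Lpl 4.33-fold. Limma's adjusted p was 0.13, 0.13, 0.23 and 0.35, so none passed. Nap1l5 (41.4-fold, adjusted p = 0.13) and Hhatl (6.32-fold, adjusted p = 0.34), also higher in experiment 2, ranked among these by p and did not pass either. In experiment 1 Nap1l5 read 4.11 and 4.99, within or near the range of controls with no target. Sarcomere genes had a median 0.76 higher in experiment 2 (camera adjusted p = 2.7e-10, and adjusted p = 0.31 with an estimated correlation), and calcium and ion-channel genes 0.42 (1.7e-05, and 0.31).

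Across the groups, CD56-140kD replicate 1 and mock replicate 2 resembled each other most (r = 0.958). The next split set this pair against CD56-140kD replicate 2 and mock replicate 1, which were less alike (r = 0.922). CD56-140kD replicate 2 correlated more closely, at 0.944, with each array of the former pair. Slc26a7, an anion transporter, read 9.71 and 9.09 in the former pair against 4.38 and 5.31, the latter near the 4.74 reached by controls with no target. In that pair the metalloproteinase inhibitor Timp2 was 13-fold and the cadherin Cdh13 7.71-fold higher. Limma's adjusted p was 0.28, 0.34 and 0.34, so none of the 3 passed. Oxidative phosphorylation genes had a median of -0.30 in this split (camera adjusted p = 2.6e-09, and adjusted p = 0.94 with an estimated correlation) and sterol synthesis genes 0.58 (5.6e-05, and 0.94). This split held 39.6% of the variance, the experiments 36% and the groups 24.4%. The 4 arrays allow 3 splits into pairs, too few for a share under 0.05. At an unadjusted p under 0.05 in limma the real split gave 263 probe sets, the split by experiments 1034 and the pairs above 1912. Both other splits thus gave more probe sets than CD56-140kD against mock.

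Mock replicate 1 lay at least 2-fold below all 3 other arrays at 1622 probe sets, against 122 to 353 for the others. The muscle gene Cav3 read 2.70 there and 9.18 to 10.48 elsewhere, and the cardiac transcription factor Gata5 2.49 against 8.91 to 10.86. Array scaling alone is argued against, since quantile normalization left 1013 probe sets against at most 390 for another array. So is RNA degraded from its 5' end, since the mean 3' minus 5' log2 difference of 4 control transcripts was 0.67 there and 0.46 to 0.98 elsewhere. A bias against genes of long genomic span and a difference of that culture or its RNA stay open, and no biological explanation was tested. A comparison of genomic spans pointed in the former direction, but its values are left out of this text and transcript lengths were not compared.

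Opposite 2-fold differences in the 2 experiments outnumbered like ones by 696 to 219. Scaling as the whole cause is argued against by 639 to 177 after quantile normalization, and noise of dim probe sets by 44 to 4 among the brightest 10%. Mock replicate 1 was the lowest array for 392 of the 548 probe sets higher in experiment 1 and lower in experiment 2, where 274 are expected if it and CD56-140kD replicate 2, the only other array that can be lowest there, were alike, and the highest for 84 of the 148 in the other direction, where 74 are. Labels exchanged in 1 experiment cannot be told apart from labels as given: of 4 kept Ncam1 probe sets 0 separated the arrays along exchanged labels and 2 along the labels, and the mouse probes may not read the transfected cDNA. An effect of CD56-140kD that differed between the experiments also stays open, untested.

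Pf4, Itgb2, Cd5l and Alox5ap, chosen after their values were seen, were highest in mock replicate 1, with Cd5l at 7.91 and Alox5ap at 8.64 there. Leukocytes in that culture are a candidate explanation. The prediction set in advance asked that over 10 of the leukocyte list's 20 genes be highest there. It also asked for a median excess over the other arrays of more than 1 log2 unit in 7 abundant macrophage genes. Neither was met: 10 of the 19 list genes on the array were highest there, and the median excess was 0.98. Among those 10, C1qc at 4.69 and Mpeg1 at 2.72 read within the range of controls with no target. The 7 macrophage genes read from 3.02 for C1qa to 8.45 for Csf1r in mock replicate 1, with Lyz2 at 5.63. Cd68, highest there at 7.36, read 7.28 in mock replicate 2. As the median of the 7 genes still lay above the other arrays, the question stays open.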
